A study of Mus musculus with 6 samples.

How the data were processed

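RNA-seq libraries of macrophages sorted from the colonic lamina propria were compared between 3 wild type and 3 transgenic samples. Per the labels' protocols, macrophages were isolated with a cell sorter, polyadenylated RNA was selected from 20 ng of total RNA, and libraries were made with a kit that is not described there as keeping strand. If strand was not kept, reads from a gene and an overlapping antisense gene could not be told apart. Groups were taken from the sample titles, which name wild type or E4BP4 transgenic and a replicate number. The genotype field of transgenic replicates 2 and 3 carries a different final digit in the gene name from that of replicate 1, while the 3 titles and the series design text name E4BP4, so the titles were followed.

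Per the submitters' processing notes, base calls were converted with bcl2fastq, reads were aligned with STAR, quantified with HOMER 4.11.1 and compared with DESeq2, and the genome build was mm10. The order and settings of these steps are not given in the sources used here. Per the file headers, the authors deposited TPM (transcript abundance scaled for length and depth) for 25124 gene rows, each named by 1 RefSeq transcript with its exon length. A second table deposited by the authors gives, for 24421 rows, log2 expression values per library, a log2 fold change, a p-value and an adjusted p-value. Its log2 values were regularized by the authors, which can shrink differences between libraries. In that table the length of 100% of rows was the gene's end less its start. Its log2 values exceeded log2 exon reads by a median of 0.12 for genes in the lowest tertile of the ratio of gene span to exon length and by 0.35 in the highest tertile, over 7878 genes. The authors' comparison thus counted over the gene span, introns included, and the TPM over exons. It had no fold change for 3537 rows.

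The test planned before the data were examined assumed read counts. The files hold TPM and log2 values, so the planned fallback was used: limma-trend (limma 3.58.1, R 4.3.3) on log2(TPM + 1), genotype as the single term, all 6 libraries, genes with a mean of at least 1 TPM in a group, Benjamini-Hochberg adjusted p below 0.05. A fold change is on the log2(TPM + 1) scale, which understates the change of genes with low values. This gave 12633 tested genes. The deposited columns sum to between 543612 and 545319 TPM. The table has 1 transcript row per gene symbol, but why the columns have these sums was not tested.

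TPM times exon length was a whole multiple of 1 step per library for 100% of the 13454 to 14213 values per library of up to 1000 reads, with a tolerance of 0.1 reads. Dividing by that step gave 13.97 to 15.06 M (1e6) reads in genes per library, 79.5% to 81.3% of the 17.25 to 18.90 M stated in the file headers. A count of 0 allows up to 3 reads, which is 0.113 to 0.122 TPM for a transcript of 2000 bases. That limit covers counting error only. The recovered reads served for depth, the spread between libraries and alternatives chosen after seeing the data. The count models planned as the main test and as an alternative were not run.

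Gene lists fixed before the data were examined (39 lists, of which 37 had at least 5 tested members) were tested with limma's camera on the same values, with an inter-gene correlation preset at 0.01. Camera was then repeated with an estimated correlation, and fry was run as a test of each list by itself. Members were also counted by adjusted p over all tested genes and adjusted over the list alone. The median of each list was set against 10000 random lists matched on mean level, a description added after seeing the data. Named genes followed a rule set before the data were examined, with TPM in place of the planned CPM. It takes Nfil3, then the 12 genes with the largest positive and the 12 with the largest negative fold change among those with adjusted p below 0.05, at least 5 TPM in the higher group and groups that do not overlap. Predicted genes, small RNAs and immunoglobulin or T cell receptor segments are skipped. It also takes up to 4 members of each list with the lowest unadjusted p, and Il12b, Il10, Il1b, Tnf, Arg1, Cx3cr1, Ccr2, Ly6c2, Adgre1, Csf1r, H2-Ab1, Dbp, Per1, Per2, Nr1d1 and Arntl whatever their p. Il6, Ifnb1, Ptges, Csf3, S100a8, Csf3r, Cd177, Padi4, Bhlhe41 and 3 lists of pancreatic genes were chosen after values were seen. Some genes that the rule takes are not reported here.

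The test was checked on simulated data made from the means of the wild type libraries, with no spread between animals. In it 50 genes were changed at each of 4 fold sizes. Of 50 genes changed by 1.25-fold 21 were recovered, of 50 changed by 1.5-fold 23, of 50 changed by 2-fold 43 and of 50 changed by 4-fold 50, among 12488 genes tested there. Of the calls, 6.80% were false. Far fewer genes were changed there than the 2766 called in the data, so these rates need not carry over to the data. Alternatives covered the pseudocount (0.1), no filter and a stricter filter of 5 TPM in 3 libraries, median-of-ratios and upper-quartile scaling, adjusted p thresholds of 0.01 and 0.10, the replicate number as a block, and leaving out each library. Added after seeing the data were limma-voom on the recovered reads, limma on the authors' log2 values, removal of a transcript length trend, rows of at least 200 bases and fold thresholds. Tables were read with Python 3.11.15 and pandas 2.3.3. Coordinates are those of the deposited tables (mm10, counted from 1).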

Results

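RNA was sequenced from macrophages sorted from the colonic lamina propria of 8-week-old C57BL/6 mice. There were 3 wild type libraries and 3 from mice that overexpress E4BP4, a basic leucine zipper transcription factor encoded by Nfil3, in macrophages. The labels give every sample the same colitis protocol: dextran sulfate sodium, a polymer that injures the colonic epithelium, at 2.0% in the water for 7 days, then 7 days of plain water and collection on day 14. The file headers state 17.25 to 18.90 M reads per library, of which 13.97 to 15.06 M could be recovered in genes. The 10 most abundant genes took 8.32% to 9.37% of these reads.

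The labels do not say whether the libraries of a group came from separate mice, so p-values measure only the spread between these libraries, which may be technical. Pairs of libraries within a group differed by a chi-square per degree of freedom of 2.06 to 2.75 and pairs across groups by 15.01 to 15.91. The variance-to-mean ratio was 2.73 at 100 to 300 reads, 2.86 at 3000 to 10000 reads and 4.32 above 10000 reads in wild type, and 2.31, 2.82 and 5.89 in transgenic libraries. A coefficient of variation of 5% between animals would have given 15.20 and 14.72 at 3000 to 10000 reads and 70.1 and 73.5 above 10000 reads. Effect sizes are therefore given first.

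**Figure D1:**
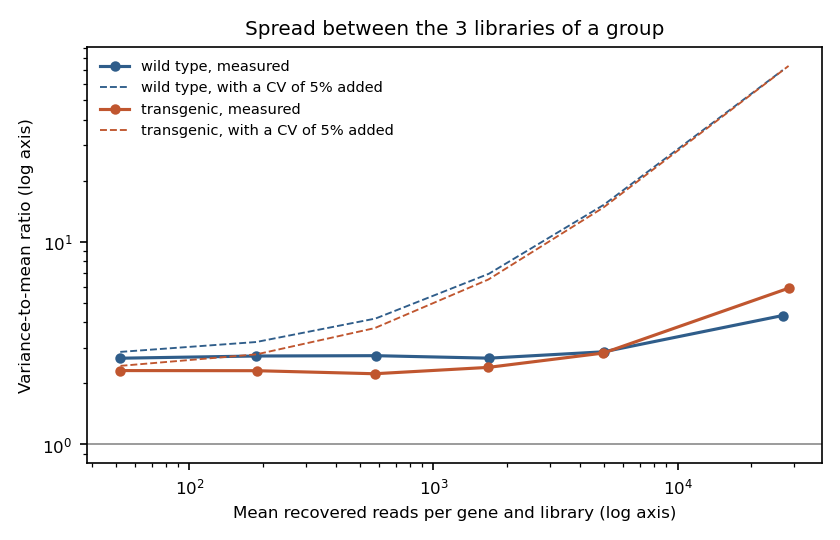
Variance-to-mean ratio of recovered reads between the 3 libraries of a group (log axis) against mean reads per gene (log axis); solid lines are measured, dashed lines add a coefficient of variation of 5%, and the grey line at 1 marks counting noise alone. The measured ratio is 2.86 in wild type and 2.82 in transgenic libraries at 3000 to 10000 reads, against 15.20 and 14.72 on the dashed lines.

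The comparison of transgenic with wild type macrophages asks which transcripts differ when E4BP4 is overexpressed in these cells. Nfil3 itself was at 117, 120 and 119 TPM in the wild type libraries and 133, 134 and 141 TPM in the transgenic ones, a ratio of means of 1.14 (log2 fold change 0.19 ± 0.029 SE, limma adjusted p = 0.00261). Retnla, a secreted resistin-like protein of alternatively activated macrophages, was 5.83-fold higher, at 117 ± 3.52 TPM in wild type and 684 ± 12.8 TPM in transgenic libraries (SD, n = 3 each). Arg1, which encodes arginase 1, was 7.09-fold lower, at 151 ± 3.49 against 21.3 ± 2.14 TPM (SD, n = 3 each). Interferon-response and antigen-presentation genes rose as groups, while hypoxia, glycolysis and neutrophil genes fell as groups, with the counts and tests given with each list.

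Of 12633 genes tested, 1100 were higher and 1666 lower in transgenic libraries (limma, adjusted p below 0.05). Of these, 195 and 339 differed by at least 1.5-fold and 67 and 92 by at least 2-fold. Groups did not overlap for 39.3% of tested genes, where chance gives 10%. With upper-quartile scaling the split was 1387 higher and 1312 lower, or 51.4% higher against 39.8%. Without transgenic replicate 2 there were 690 genes higher and without transgenic replicate 3 there were 719, while genes lower numbered 1231 to 1350 over the 6 libraries left out in turn.

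**Figure D2:**
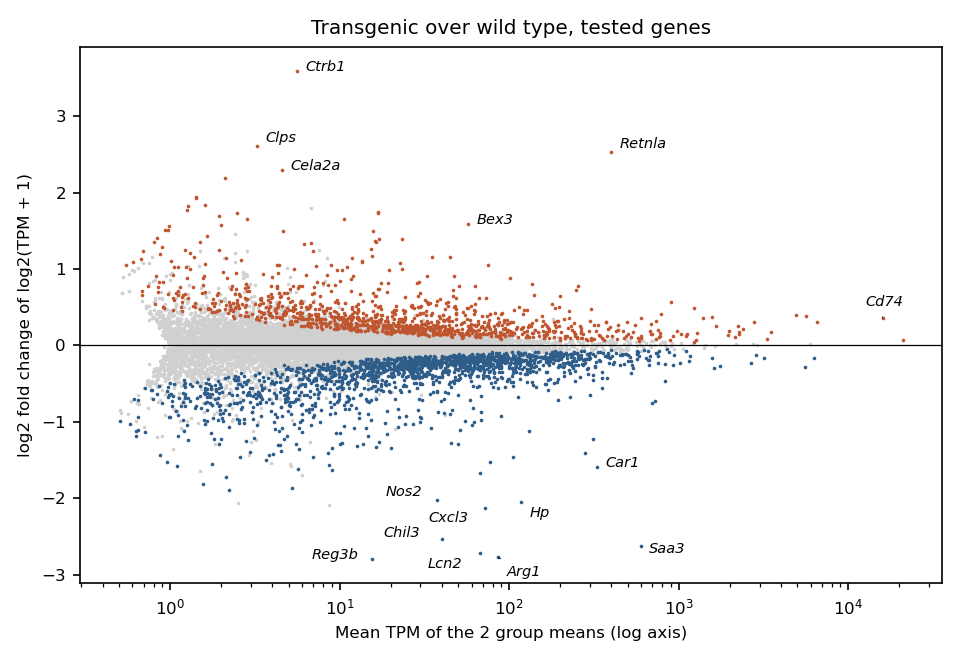
Fold change of each of the 12633 tested genes, on the log2(TPM + 1) scale as transgenic over wild type, against the mean TPM (log axis); the 1100 genes called higher are orange, the 1666 called lower blue and the rest grey. Retnla stands at 2.53 and Arg1 at -2.77.

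Nfil3 lies on chromosome 13 at 52967209 to 52981039, minus strand (NM_017373, mm10), and its row counts exons of the mouse transcript. The labels do not give the species or the untranslated regions of the transgene, so a transgene that differs from this transcript may be counted in part only. The exact two-sided permutation test of the TPM means gave p = 0.10, the smallest that 3 against 3 libraries allow. Of the list of circadian clock and PAR bZIP genes, 2 of 18 tested members rose (Nfil3 and Per1) and 3 fell (Bhlhe40, Cry1 and Bhlhe41). Bhlhe41 was named after its value was seen, and its call (limma adjusted p = 0.0376) was lost when any 1 of the 6 libraries was left out, with an adjusted p of 0.0599 to 0.106, and with no filter on low values (0.0732). The counts adjusted over the list alone were the same, 2 and 3. The list was not called (camera adjusted p = 0.632), with a median of 0.03 and a mean of -0.01. Dbp, whose product binds the same DNA element as E4BP4, was at 13.1 ± 0.743 and 12.9 ± 0.0785 TPM (SD, n = 3 each; limma adjusted p = 0.863). Nr1d1 was at 12.0 TPM in both groups (limma adjusted p = 0.996), Per2 at 6.91 and 7.25 TPM (0.589) and Arntl at 8.43 and 9.34 TPM (0.268). Arntl was called in the authors' deposited table (adjusted p = 0.0245) and under an alternative here.

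**Figure D3:**
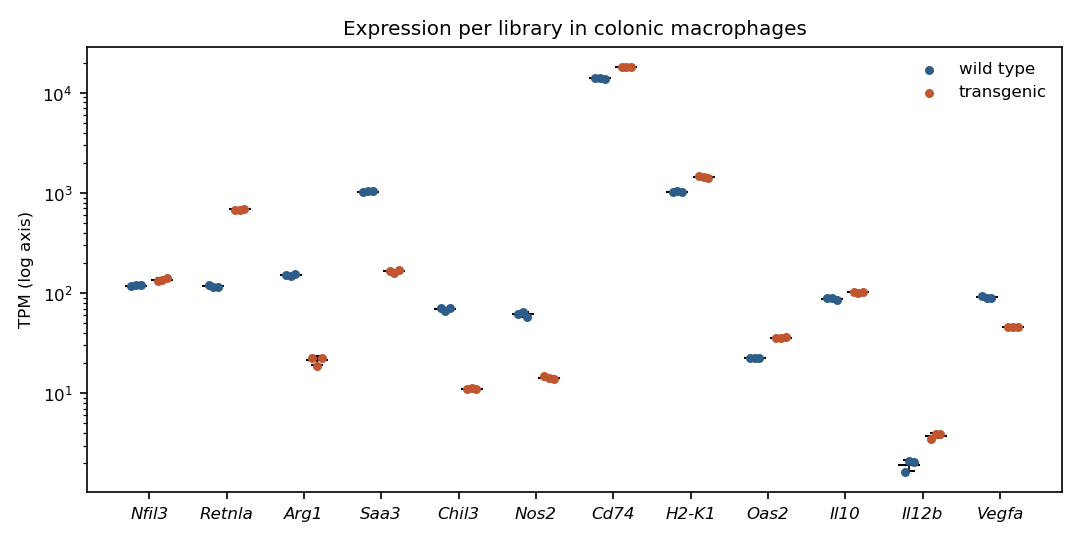
TPM (log axis) of 12 genes in each of the 3 wild type (blue) and 3 transgenic (orange) libraries; points are libraries, and black marks give the mean and SD. Libraries of a group lie close together, with Arg1 at 151 TPM in wild type and 21.3 TPM in transgenic libraries, and Retnla at 117 and 684 TPM.

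The genes with the largest falls included acute-phase and antimicrobial genes. Saa3, a serum amyloid A protein, was at 1028 ± 15.03 TPM in wild type and 165 ± 4.59 TPM in transgenic libraries (SD, n = 3 each), 6.23-fold lower. Lcn2, which binds bacterial siderophores, fell by 2.72 on the log2 scale and Hp, encoding haptoglobin, fell by 2.05. Chil3, a chitinase-like protein, fell by 2.53, the neutrophil chemokine gene Cxcl3 fell by 2.13 and Nos2, inducible nitric oxide synthase, fell by 2.02. Reg3b and Reg3g, antimicrobial lectins of the epithelium, fell by 2.80 and 1.87, and the colonocyte carbonic anhydrase gene Car1 fell from 497 to 164 TPM. Mmp8 and Egln3 fell by 1.63 and 1.61. The highest limma adjusted p among these 11 genes and Arg1 was 0.000345. Arg1 lies on chromosome 10 at 24915207 to 24927470 (NM_007482), Saa3 on chromosome 7 at 46711998 to 46715676 (NM_011315) and Retnla on chromosome 16 at 48842609 to 48844461 (NM_020509), all mm10.

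Among the genes with the largest rises other than Retnla, Ctrb1, Clps, Cela2a, Sycn and Spink1 are known as pancreatic exocrine genes. Ctrb1 was listed at 0 in the 3 wild type libraries and at 11.1 ± 2.09 TPM in the transgenic ones (SD, n = 3). Clps stood at 0.197 and 6.34 TPM, from 4 and 133 reads over 3 libraries each, and Cela2a at 0.900 and 8.30 TPM. Bex3 rose from 28.0 to 86.6 TPM, Wfdc2 from 1.96 to 7.30 TPM and the guanylate-binding protein gene Gbp2b from 8.61 to 23.7 TPM. Ear2, Ear3 and Ear12 encode eosinophil-associated ribonucleases and rose, Ear2 from 7.83 to 23.6 TPM and Ear3 and Ear12 by 1.74 and 1.75 on the log2 scale. Ear3 and Ear12 are listed at the same position (chromosome 14 at 44102887 to 44103357, mm10), which lies within that of Ear2 (44102654 to 44103531). Ear3 and Ear12 had equal transgenic values, 26.5 TPM. The 3 rows thus cover overlapping sequence and are not 3 separate rises, and which of these genes the reads came from is uncertain. The highest limma adjusted p among these 11 genes and Retnla was 0.00236.

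Interferon-response genes rose together. Of 31 tested type I interferon response genes 26 rose and 0 fell, or 29 and 0 adjusted over the list alone (median log2 fold change 0.42, camera adjusted p = 7.97e-18). Oas2, an antiviral nucleotide synthetase, rose from 22.4 ± 0.119 to 35.8 ± 0.493 TPM (SD, n = 3 each), and Rtp4, Ifi27l2a and Oasl1 rose by 0.82, 0.81 and 0.92 on the log2 scale. In the interferon-gamma response list 20 of 27 rose and 1 fell, or 22 and 1 adjusted over the list alone (median 0.34, camera adjusted p = 4.22e-12). Its examples were Irf1, at 107 and 149 TPM, Tap1, at 49.0 and 70.7 TPM, and Gbp2, at 29.9 and 45.2 TPM. T cell, NK cell and ILC markers were higher in the same libraries: 10 of 27 rose and 0 fell, or 13 and 1 adjusted over the list alone (median 0.33, camera adjusted p = 2.92e-06). Klrk1 and Cd8a stood at 0.797 and 2.05 TPM in wild type and at 2.38 and 3.65 TPM in transgenic libraries.

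Antigen-presentation genes rose as well. Lists share members, as Tap1 is in the class I and interferon-gamma lists and Ciita in the class II and interferon-gamma lists. The list results are therefore not independent. For MHC class I, 14 of 17 members rose and 0 fell, or 15 and 0 adjusted over the list alone (median 0.42, camera adjusted p = 4.06e-15). H2-K1 rose from 1029 ± 8.88 to 1440 ± 27.4 TPM and H2-D1 from 1219 ± 6.58 to 1557 ± 22.3 TPM (SD, n = 3 each), with reads that related class I genes may share. For MHC class II, 9 of 16 rose and 2 fell, or 12 and 2 adjusted over the list alone (median 0.23, camera adjusted p = 3.25e-08). Cd74, the invariant chain, was at 13976 ± 93.1 TPM and 17931 ± 44.7 TPM (SD, n = 3 each), H2-Ab1 at 5893 and 7287 TPM, and Ciita, the class II transactivator, at 51.0 and 75.1 TPM. Conventional dendritic cell markers, which also carry class II, rose in the same libraries: 8 of 27 rose and 2 fell, or 12 and 4 adjusted over the list alone (median 0.16, camera adjusted p = 0.000868). Batf3, Dpp4 and Irf4 rose by 0.64, 0.78 and 0.45 on the log2 scale, and Fscn1 fell by 0.65. Plasmacytoid dendritic cell markers gave 6 higher and 0 lower of 12, the same adjusted over the list alone (median 0.23, camera adjusted p = 0.00329). With an estimated correlation their adjusted p was 0.0633, the highest over the camera alternatives, whose lowest was 0.00200.

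Of 32 intestinal resident macrophage genes 18 rose and 5 fell, or 18 and 6 adjusted over the list alone (median 0.12, camera adjusted p = 5.85e-06). The scavenger receptor gene Cd163 rose from 89.2 to 124 TPM, Cd209f from 32.5 to 61.9 TPM and the folate receptor gene Folr2 from 155 to 217 TPM. Adgre1, which encodes F4/80, rose by 0.24, the growth factor receptor gene Csf1r by 0.15 and Cx3cr1 by 0.13 on the log2 scale. Of 25 monocyte genes 4 rose and 14 fell, or 7 and 15 adjusted over the list alone (median -0.23, camera adjusted p = 0.00053). Thbs1 fell from 874 to 517 TPM and Clec4e from 95.9 to 65.7 TPM, beside Chil3 and Hp. The chemokine receptor gene Ccr2 rose by 0.26 on the log2 scale (limma adjusted p = 0.000487), and Ly6c2 was at 13.6 ± 2.16 and 13.4 ± 1.64 TPM (SD, n = 3 each; limma adjusted p = 0.946).

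Hypoxia-response genes fell, 17 of 23 with 0 rising, or 21 and 0 adjusted over the list alone (median -0.55, camera adjusted p = 1.98e-14). Vegfa, the endothelial growth factor gene, fell from 90.8 ± 2.68 to 45.6 ± 0.124 TPM (SD, n = 3 each), and Ddit4 from 88.6 to 48.1 TPM. Glycolysis genes fell, 15 of 22 with 1 rising, or 16 and 2 adjusted over the list alone (median -0.43, camera adjusted p = 2.77e-10). The lactate exporter gene Slc16a3 fell from 83.3 to 41.3 TPM, the glucose transporter gene Slc2a1 from 78.6 to 44.1 TPM and Ldha from 359 to 263 TPM. Of 28 genes of extracellular matrix remodelling 18 fell and 1 rose, or 21 and 2 adjusted over the list alone (median -0.41, camera adjusted p = 1.6e-08). The gelatinase gene Mmp9 fell from 181 to 82.4 TPM and Col4a1 from 20.0 to 7.59 TPM. Cholesterol synthesis genes fell, 15 of 24 with 0 rising, or 17 and 0 adjusted over the list alone (median -0.23, camera adjusted p = 2.06e-05), with Sqle, which encodes squalene epoxidase, at 15.6 and 11.5 TPM. In the unfolded protein response 15 of 23 fell and 4 rose, or 17 and 4 adjusted over the list alone (median -0.16, camera adjusted p = 3.52e-05). The chaperone gene Hyou1 fell by 0.48 and Atf3 rose by 0.42 on the log2 scale. Oxidative phosphorylation genes fell by little, 15 of 63 with 0 rising over all genes and over the list alone (median -0.08, camera adjusted p = 0.000289), with Cox6a1 at 328 and 254 TPM. Their median lay within the middle 95% of 10000 random lists matched on mean level (percentile 7.66), while the medians of the other 22 lists called by camera lay outside it.

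Markers of neutrophils, epithelium, fibroblasts and endothelium fell in the same libraries as these groups. Neutrophil markers fell, 18 of 21 with 0 rising, the same adjusted over the list alone (median -0.84, camera adjusted p = 1.98e-14). S100a9 fell from 439 ± 7.52 to 187 ± 14.4 TPM (SD, n = 3 each), Clec4d from 73.1 to 36.2 TPM, and S100a8 from 409 to 154 TPM. Csf3r, Cd177 and Padi4 differed by -0.05, 0.12 and -0.04 on the log2 scale (limma adjusted p = 0.428, 0.323 and 0.764), and the sign of Padi4 flipped without transgenic replicate 2. S100a8 and these 3 members were named after their values were seen. Of 37 epithelial markers 24 fell and 4 rose, or 27 and 6 adjusted over the list alone (median -0.41, camera adjusted p = 6.97e-08), with Krt20 at 26.6 and 11.4 TPM. Of 31 fibroblast and smooth muscle markers 18 fell and 0 rose, the same adjusted over the list alone (median -0.41, camera adjusted p = 1.01e-06). Col3a1 was at 51.9 and 36.1 TPM. Of 19 endothelial markers 11 fell and 2 rose, or 13 and 2 adjusted over the list alone (median -0.49, camera adjusted p = 0.00291). That call was lost with an estimated correlation (adjusted p = 0.0636), and the adjusted p ranged from 0.000502 to 0.621 over the camera alternatives. Plvap, of fenestrated vessels, fell by 1.28 on the log2 scale. Of 10 erythrocyte and platelet markers 7 rose and 1 fell, or 7 and 2 adjusted over the list alone (median 0.80, camera adjusted p = 0.00254), an adjusted p of 0.181 with an estimated correlation, the highest over the camera alternatives, whose lowest was 0.000278. Hbb-b1 and Hba-a2 stood at 8.31 and 6.12 TPM in wild type and at 18.9 and 13.1 TPM in transgenic libraries. Hbb-b1 and Hbb-bs are listed at nearly the same position (chromosome 7 at 103826532 to 103827929 and 103826523 to 103827928, mm10). So are Hba-a1 and Hba-a2 (chromosome 11 at 32283672 to 32284486 and 32283675 to 32284493). These rows cover overlapping sequence, so the 7 called rises are not 7 separate rises. The list's median and test count each row as a member.

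Inflammatory mediators moved both ways. Of 23 pro-inflammatory cytokines and mediators 11 fell and 5 rose, or 11 and 6 adjusted over the list alone (median -0.22, camera adjusted p = 0.015). The call was lost with an estimated correlation (adjusted p = 0.0787, the highest over the camera alternatives, whose lowest was 3.6e-06). Il1b fell from 2869 ± 8.29 to 2452 ± 14.04 TPM and Il1a from 124 to 85.9 TPM (SD, n = 3 each), and Acod1, which makes itaconate, fell by 0.64 on the log2 scale. Il12b, the shared subunit of interleukins 12 and 23, rose from 1.92 ± 0.256 to 3.78 ± 0.237 TPM (SD, n = 3 each). Il6 rose by 1.34 on the log2 scale, Ifnb1 rose from 0.374 to 2.08 TPM, and Ptges and Csf3 fell, from 5.92 to 1.45 and from 7.25 to 2.59 TPM. These 4 genes were named after their values were seen. Ifnb1 rests on 11 and 62 reads per group, and its call was lost without wild type replicate 1 or 3 (limma adjusted p = 0.0722 and 0.0719) and without transgenic replicate 2 or 3 (0.071 and 0.0817). Tnf was at 127 ± 1.97 and 131 ± 2.31 TPM (SD, n = 3 each; limma adjusted p = 0.197). The anti-inflammatory cytokine gene Il10 rose from 87.8 ± 2.72 to 102 ± 1.38 TPM (SD, n = 3 each; limma adjusted p = 0.00262). Of 24 anti-inflammatory and tolerance mediators 8 rose and 9 fell, the same adjusted over the list alone (camera adjusted p = 0.885), with Tnfaip3 up by 0.32 and Il1rn, the interleukin 1 receptor antagonist gene, down from 282 to 176 TPM. Of 24 alternatively activated macrophage genes 9 rose and 6 fell, or 11 and 6 adjusted over the list alone (camera adjusted p = 0.0765). Retnla rose while Arg1, Chil3 and Tgm2 fell. Of 21 tissue repair and growth factor genes 9 fell and 4 rose, or 11 and 5 adjusted over the list alone (camera adjusted p = 0.0241), an adjusted p of 0.181 with an estimated correlation, the highest over the camera alternatives, whose lowest was 0.00365. The osteopontin gene Spp1 fell from 116 to 39.4 TPM. Immediate-early and dissociation-induced genes, a list set as a check on handling, gave 17 higher and 7 lower of 34. Adjusted over the list alone the counts were 18 and 8 (median 0.11, camera adjusted p = 1.18e-05), with Hspa1a at 187 and 311 TPM. Whether handling or the state of the cells caused this was not tested.

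**Figure D4:**
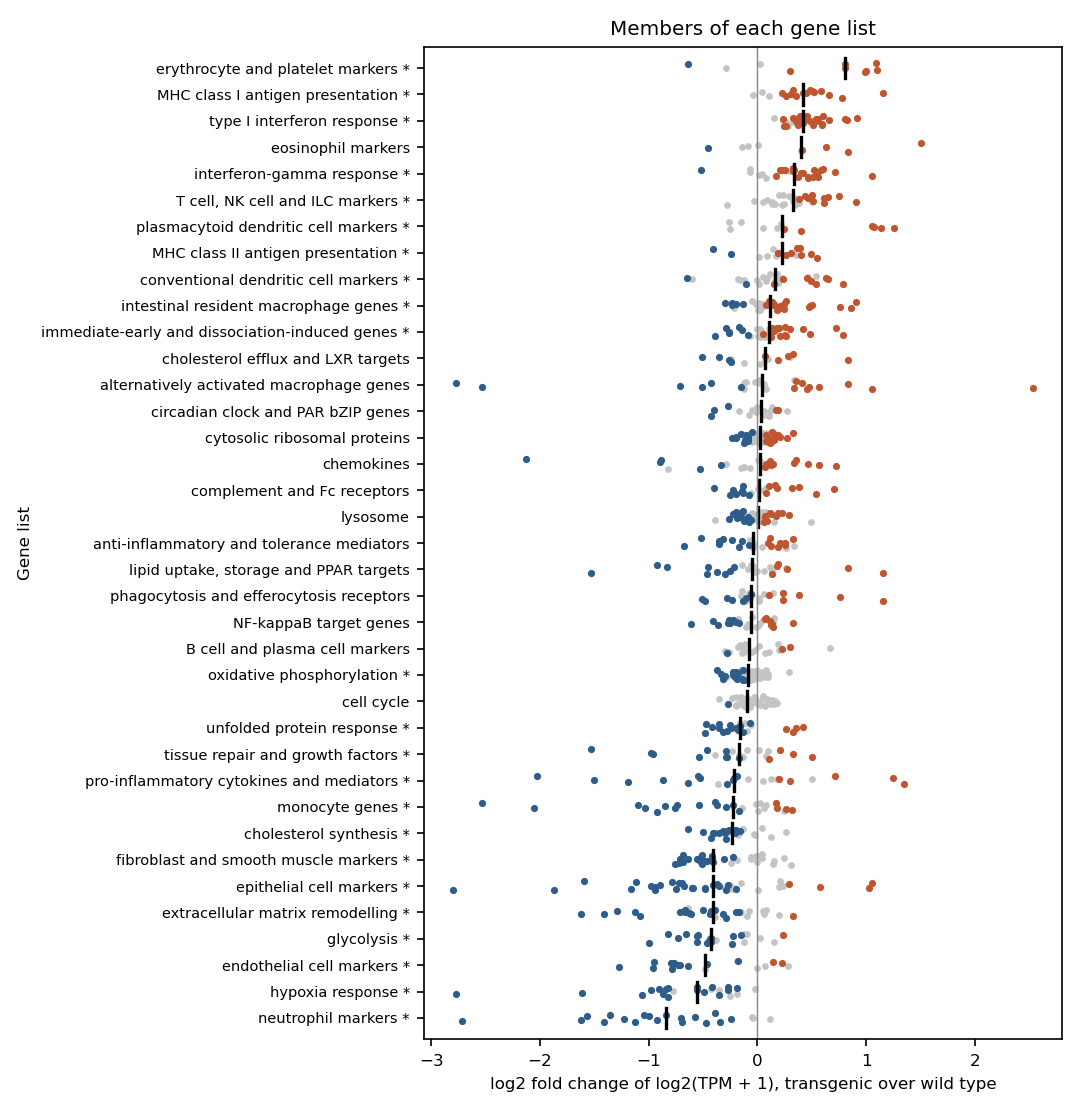
Log2 fold change, on the log2(TPM + 1) scale as transgenic over wild type, of the tested members of each of the 37 lists with at least 5 tested members; orange and blue points were called higher and lower, grey points were not called, black bars are medians and a star marks a list called by camera. Medians run from -0.84 for neutrophil markers to 0.80 for erythrocyte and platelet markers, a list with overlapping globin rows.

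The authors' deposited table calls 2343 rows higher and 2756 lower in transgenic libraries at an adjusted p below 0.05. Of 2677 genes called here and present in both tests, 2429 were called in the authors' deposited table as well, and 0 of these had the opposite sign. Fold changes correlated across 12097 genes, which are not independent replicates (Pearson's r = 0.871, Spearman's rho = 0.929). In the authors' deposited table the log2 fold change was 0.09 for Nfil3 (adjusted p = 0.0169), -2.85 for Arg1, 2.49 for Retnla and -2.67 for Saa3.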

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

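Chosen after seeing the data were limma-voom on the recovered reads, limma on the authors' log2 values, removal of a length trend, rows of at least 200 bases and the fold thresholds; the others were planned. Of 157 named genes called by limma 152 kept call and direction over 19 alternatives, those other than the 0.01 and fold thresholds, and Apoe, Bhlhe41, Birc5, Ifnb1 and Nkg7 lost the call under at least 1; 0 changed sign. At 0.01 Bhlhe41, Birc5, Cry1 and Ifnb1 lost the call, and 76 and 114 named genes did with a fold of at least 1.5 and 2. Of 17 named genes not called, 7 were called under at least 1 of the 19 alternatives, Arntl and Mcpt2 among them. Of 23 lists called by camera 18 kept the call. Pro-inflammatory mediators, tissue repair, plasmacytoid dendritic cell, endothelial and erythrocyte lists lost it with an estimated correlation, and tissue repair and endothelial markers also at 5 TPM in 3 libraries. The TMM-based fits and the edgeR and DESeq2 tests were not run; of the count-based fits, limma-voom alone was run, on the recovered reads. Scaling by library size alone was run only with limma-voom on the recovered reads, and rows per gene were not varied, since each symbol has 1 row. Depth limits genes near the floor, such as Ifnb1.

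At an adjusted p of 0.01 there were 514 genes higher and 902 lower, and with a fold of at least 1.5 or 2 there were 195 and 339, or 67 and 92, fold limits that Nfil3 at 0.19 did not pass. Limma-voom called 1794 genes higher, or 1802 with quality weights, and limma on the authors' log2 values called 2783 lower. The cause was not tested. Leaving out 1 library, which leaves fewer samples, gave 690 genes higher without transgenic replicate 2, 719 without transgenic replicate 3 and at most 874.

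Signs changed for Dbp, Ly6c2, Nr1d1 and Padi4 and for 6 list medians, none called by the main test. Median-of-ratios and upper-quartile factors shift all genes alike, from a median of -0.012 to 0.0050 and 0.019, which accounts for the changes of sign there; the cause of the others was not tested. With median-of-ratios factors the log2 fold changes of Ly6c2, Dbp and Nr1d1 were 0.0023, 0.00015 and 0.017, and with upper-quartile factors 0.017, 0.015 and 0.032. With limma-voom they were 0.0045, 0.0010 and 0.016. With quality weights Dbp and Nr1d1 were at 0.0012 and 0.021, with library totals only Nr1d1 was at 0.0028, and with the length trend removed Ly6c2 was at 0.018. With 1 library left out Ly6c2 ran from -0.14 to 0.073, Dbp from -0.042 to 0.026, Nr1d1 from -0.055 to 0.049 and Padi4 from -0.079 to 0.016. With no filter the medians of anti-inflammatory mediators and eosinophil markers were 0.0022 and -0.022. The complement median was -0.027 at 5 TPM in 3 libraries. On the authors' log2 values the medians were 0.028 for anti-inflammatory mediators, -0.019 for complement, -0.038 for lysosome and -0.027 for ribosomal proteins, and lysosome was at -0.0084 with the length trend removed. With 1 library left out chemokines ran from -0.0060 to 0.079, complement from -0.0056 to 0.017 and lysosome from -0.0045 to 0.015.

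With the replicate number as a block there were 922 genes higher and 1457 lower, 24 lists were called and Nfil3 stood at 0.19. The block ended the call of Bhlhe41 (limma adjusted p = 0.0616) and gave a call to Mcpt2 and to ribosomal proteins (camera adjusted p = 0.0398). Deviations of same-numbered libraries correlated across genes at -0.013, -0.043 and 0.032, and 1 of 3 numbers correlated best with its own, so the numbers were not used as pairs.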

Other observations

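The tests of the weighed patterns and of the pancreatic gene lists were chosen after the result was seen. Several groups of macrophage genes had members moving both ways and were not called by camera. By fry, which compares a list with no change and not with other genes, 31 of 37 lists moved one way on balance, among them NF-kappaB targets (adjusted p = 0.00102), phagocytosis receptors (0.027), lipid uptake genes (0.0118), LXR targets (0.038) and complement (0.0428). Counted at an adjusted p below 0.05, camera alternatives called chemokines and NF-kappaB targets under 2 settings each and LXR targets under 3. Alternatively activated macrophage genes, cell cycle genes and eosinophil markers were called under 1 each. The looser adjusted p threshold, not counted there, also called alternatively activated macrophage genes (camera adjusted p = 0.0765). Of 24 phagocytosis and efferocytosis receptors 6 rose and 7 fell, or 7 and 8 adjusted over the list alone (camera adjusted p = 0.832, median -0.06, mean 0.03): the scavenger receptor gene Cd36 rose from 27.3 to 61.9 TPM and Msr1 fell from 162 to 113 TPM. Of 26 lipid uptake and PPAR targets 6 rose and 9 fell, the same adjusted over the list alone (camera adjusted p = 0.832), with Fabp5 down from 118 to 61.6 TPM. Of 15 cholesterol efflux and LXR targets 5 rose and 4 fell, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.295), with the lipoprotein lipase gene Lpl up from 20.8 to 37.8 TPM and the receptor gene Nr1h3 down from 35.1 to 24.3 TPM. Of 25 chemokines 10 rose and 5 fell, or 12 and 7 adjusted over the list alone (camera adjusted p = 0.151, median 0.02, mean -0.13): Ccl8 rose from 727 to 1079 TPM and Ccl5 and Cxcl10 rose by 0.72 and 0.46 on the log2 scale, while Cxcl3 fell. Of 28 NF-kappaB targets 7 rose and 10 fell, or 7 and 12 adjusted over the list alone (camera adjusted p = 0.142), with Sod2 down by a log2 fold change of -0.61. Complement and Fc receptors gave 8 higher and 8 lower of 20, the same adjusted over the list alone (camera adjusted p = 0.686), with C3 at 85.3 and 64.6 TPM and the C5a receptor gene C5ar1 at 298 and 250.4 TPM. Lysosome genes gave 10 higher and 12 lower of 43, or 12 and 15 adjusted over the list alone (camera adjusted p = 0.832, median 0.0045, mean -0.0027).

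Ribosomal protein genes gave 17 higher and 14 lower of 76, or 17 and 15 adjusted over the list alone. The list was not called (median 0.02, camera adjusted p = 0.0822). At an adjusted p below 0.05, 7 of 21 camera alternatives called this list (adjusted p 0.000137 to 0.590). The looser adjusted p threshold, not counted among the 7, called it as well. Of 45 cell cycle genes 0 rose and 1 fell, or 0 and 0 adjusted over the list alone (camera adjusted p = 0.125). That 1 was Birc5, at 13.6 and 11.2 TPM (limma adjusted p = 0.0441), a call lost on leaving out any 1 library other than transgenic replicate 2 (adjusted p 0.052 to 0.132). Of 9 eosinophil markers 4 rose and 1 fell, or 4 and 2 adjusted over the list alone (median 0.40, camera adjusted p = 0.119), with Alox15 at 5.01 and 9.72 TPM. Members too low to test were not higher in transgenic libraries. Epx, Ear1 and Ear6 had 0 reads, and Prg3 had 4 wild type and 0 transgenic reads, Ccr3 98 and 81 and Il5ra 32 and 27. B cell and plasma cell markers gave 2 higher and 1 lower of 20, the same adjusted over the list alone (median -0.08, test direction up, camera adjusted p = 0.832), with Jchain at 165 and 204 TPM. Of 4 tested mast cell and basophil markers Mcpt1 rose from 3.81 to 10.1 TPM and Hdc fell from 28.6 to 15.6 TPM, 2 and 1 adjusted over the list alone. Of 2 tested enteric glia markers 0 were called and 1 was lower adjusted over the list alone. Both lists were too short for the list test.

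The libraries of a group differed very little. A coefficient of variation beyond library noise of at most 1.12% at over 3000 reads is what libraries from 1 shared or pooled RNA sample may give. Separate animals whose expression differs by at least 5% are argued against, since the variance-to-mean ratio reached 0.192 of the level that needs. Separate animals that differ by less stay open.

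Arg1, Saa3, Chil3, Cxcl3, Hp, Nos2 and Egln3 fell along with markers of neutrophils, epithelium and fibroblasts. A lower share of every other cell type at once is argued against. With an estimated correlation 2 lists of other cell types were called higher (T cell and conventional dendritic cell) beside 3 lower. A lower share of only some types, such as epithelium and fibroblasts, stays open. Fewer neutrophils stay open. A macrophage sort should remove them, but the sorted libraries held markers of other cell types, as Car1 at 497 and Col3a1 at 51.9 TPM in wild type. The median of the 7 genes lay -1.29 from that of the neutrophil markers, but the 7 were picked as large falls, which fixes that difference. Of 21 neutrophil markers 18 fell, with log2 fold changes of -2.72 for Lcn2, -1.04 for Retnlg and -0.47 for Ly6g. The 3 not called, Csf3r, Cd177 and Padi4, differed by -0.05, 0.12 and -0.04. Fewer recruited monocytes cannot be told apart from a change within macrophages, because Ccr2 rose by 0.26 on the log2 scale while Ly6c2 was not called and the monocyte list fell. An effect of the transgene on these genes stays open as a hypothesis, untested beyond the comparison of genotypes.

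Pancreatic exocrine transcripts stood above every wild type library in the 3 transgenic libraries. Pancreas tissue or its RNA may be a source. Of 30 acinar and ductal genes 19 met that rule with a mean of at least 10 reads. Of these, 8 had 0 wild type reads, as Ctrb1 with 119, 146 and 112 transgenic reads and Pnlip with 60, 42 and 61. The 19 include Ctrb1, Clps, Cela2a, Sycn and Spink1, which were already picked as large rises. A macrophage sort should remove such cells, but markers of other cell types were present, as Car1 at 497 TPM in wild type libraries. Some abundant pancreatic genes were absent from these reads, as Amy2a5, Prss1 and Cela3a had 0 reads in all 6 libraries. Of their relatives, Prss2 had 44, 41 and 45 transgenic reads, Cela3b 14, 24 and 19, and Amy2b 1, 0 and 0. How reads that fit several related genes were counted is not given, so these zeros cannot show that the transcripts were absent. Of 6 islet hormone genes 0 met the rule. Reads shared between related protease genes are argued against as the whole cause, since 9 of 15 genes outside the protease families met it. Clps, Sycn and Spink1 among them were already picked as large rises, while Pnlip, Pnliprp1, Cel, Reg1, Reg2 and Rnase1 were not. Expression by cells of the transgenic animals was not tested and stays open.

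The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The other 9 each mix the genotypes, which puts the difference between them into the spread, so they are no reference for unchanged libraries. The real split called 2766 genes by limma and the highest other 0, with 4439 and at most 365 genes at an unadjusted p under 0.05. It called 23 lists by camera and the highest other 11. In each count, 1 split reached the real value, the real one itself.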
